A study of Coprinopsis cinerea with 4 samples.

How the data were processed

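RNA of 4 libraries was analysed, 2 of oidia and 2 of hyphae, grouped by the stage in the sample titles. Per the labels' protocols, RNA was poly(A)-selected, and libraries were made with the SOLiD Total RNA-seq kit for oidia and the NEBNext Ultra kit for Illumina for hyphae. Kit and stage therefore cannot be separated. Per the submitters' processing notes, TopHat, Bowtie 0.12.7 and DESeq were used. The genome build, the annotation, the counter, and its strand and multimapping settings are not given in the sources used here, so overlapping, antisense and near-identical features could not be told apart.

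Per the file headers and the accompanying notes, the authors deposited read counts per gene or element and library, and these counts were used for the tests. Element rows overlap genes, so a read can be counted in more than 1 row. Genes took between 46.1% and 47.3% of the reads of all rows. The deposited mean signal of each stage equalled the counts divided by median-of-ratios size factors in all 27856 rows, within a relative tolerance of 1e-06. The deposited fold column and the deposited log2 column are described by the authors as hyphae over oidia. By the values they are oidia over hyphae, in all 21769 rows with a finite value, so directions were taken from the counts. A further log2 column of the deposited table adds 0.1 to both means. The deposited p-value columns come from the authors' DESeq run.

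Genes and elements were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood method, with TMM factors from the genes (1.71, 1.70, 0.589 and 0.580 for hyphae 1 and 2 and oidia 1 and 2), filterByExpr, and Benjamini-Hochberg adjusted p under 0.05. Elements were scaled by the gene-based sizes. Class sums were fitted beside the genes where a class had at least 10 reads. Standard errors of log2 fold changes were taken from the fold change and the F statistic, and are approximate. CPM values use the TMM-scaled sizes. Genes at 0 in a stage have a bound against a floor of 3 reads over that stage, and ratios with few reads have 95% exact (Clopper-Pearson) intervals. These cover counting error only, since the reads had no molecular identifiers. Lists were tested with camera on voom values (limma 3.58.1) at an inter-gene correlation of 0.01, for lists with at least 5 tested members.

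Named genes were fixed by rule before the data were examined: an adjusted p under 0.05, a mean normalized count of at least 100, no overlap between stages (33.3% by chance for 2 against 2), and the 5 largest changes each way. A part of the rule for genes with informative names found none, since the gene list of the reference assembly held no symbol other than the locus tag. Of the gene identifiers 13340 matched it and 2 did not. Of 43 keyword lists fixed in advance, 2 found members, all in element names except the 1 TET gene given by identifier. The other 41 lists, among them the stage markers, could not be evaluated. The element classes, the leading genes by abundance and the tests on them were chosen after the data were seen.

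Replicates of a stage differed by more than sampling noise (chi-square per degree of freedom 1.28 for hyphae over 9555 genes and 3.63 for oidia over 8011 genes). Their biological coefficient of variation was 4.12%. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The fit was tested on simulated counts for 9866 genes with 200 changed genes. It recovered 42% of 50 genes changed 1.5-fold, 86% of those changed 2-fold, 86% at 4-fold and 100% at 8-fold. These are shares of all 50 genes changed by each fold, of which 46, 46, 45 and 50 had enough reads to test. Of 161 calls 4 were false. The simulation changed far fewer genes than changed in the data, in random directions, and gave both stages the same dispersion. Its rates therefore need not hold for these libraries.

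Alternatives were other scalings, the DESeq2 1.42.0 Wald test, other filters and thresholds, the replicate number as a block, leaving out each library, the authors' adjusted p, fry and an estimated correlation. Total-count scaling, cyclic loess with limma-voom and a fit of all rows together were added after the data were seen. Correction for GC content was not run, as no genome sequence was used here.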

Results

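RNA sequencing compared 2 stages of the mushroom Coprinopsis cinerea, strain Okayama 7#130. Oidia are single-celled asexual spores, and hyphae are the growing filaments of the vegetative mycelium. Each stage had 2 libraries of poly(A)-selected RNA. The series belongs to work on TET/JBP proteins, a family of dioxygenases whose TET members oxidise methylcytosine in DNA, and its RNA arm sets the transcripts of the 2 stages side by side. The table held 13342 genes and 14514 further rows for genomic elements (regions classed as orthologous, paralogous or orphan, repeats, centromeres and transposon families). Reads assigned to genes numbered 4586306 and 3546635 in hyphae replicates 1 and 2, and 7519091 and 6128727 in oidia replicates 1 and 2. Oidia were prepared with a SOLiD kit and hyphae with an Illumina kit, so stage and library kit cannot be told apart in any difference below.

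Of the 5 most abundant genes of each stage, picked after their values were seen, 1 was shared. In oidia CC1G_04673 alone took 7.95% ± 0.241 of gene reads and CC1G_13924 took 7.29% ± 0.271, against 0.0197% ± 0.000300 and 0.0434% ± 0.000468 in hyphae (SD, n = 2 each). CC1G_03927 and CC1G_11300 took 4.47% ± 0.469 and 3.71% ± 0.148 of oidia gene reads (SD, n = 2 each), with log2 fold changes (hyphae over oidia) of -8.93 and -9.33. In hyphae CC1G_10398 led with 3.80% ± 0.0397 of gene reads (SD, n = 2) and a log2 fold change of 8.44. CC1G_08745, CC1G_10394 and CC1G_02388 were also among the 5 leading hyphal genes, with log2 fold changes of 3.80, 3.47 and 6.65. CC1G_10834 was among the 5 leading genes of both stages, at 2.33% ± 0.00757 of hyphal and 4.97% ± 0.377 of oidia gene reads (SD, n = 2 each). Its log2 fold change of -2.64 turned to 0.27 under cyclic loess normalization, which was added after the data were seen and also moved the others. It gave -7.95 for CC1G_04673, -6.58 for CC1G_13924, -6.72 for CC1G_03927, -7.23 for CC1G_11300, 10.28 for CC1G_10398, 5.82 for CC1G_08745, 5.51 for CC1G_10394 and 8.08 for CC1G_02388. Genes are given by locus identifier, because the sources used here gave them no product names.

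Further genes were named by a rule fixed before the data were examined, with 5 in each direction. CC1G_05776 had 595 ± 34.6 CPM (counts scaled to the library's TMM-adjusted size) in hyphae (SD, n = 2) and no read in oidia, at least 1575-fold higher against a floor of 3 reads over the stage (lower limit 1280 by the two-sided 95% exact interval). CC1G_03893 reached 678 ± 0.780 CPM in hyphae against 0.565 ± 0.799 in oidia (SD, n = 2 each), a scaled read ratio of 1082 (95% exact interval 464 to 3334). All 5 of its oidia reads lay in replicate 1, and its log2 fold change of 10.03 became 14.95 without oidia replicate 1 and 9.19 without oidia replicate 2. The other named genes of this direction, CC1G_02182, CC1G_12454 and CC1G_15645, had 1 or 2 oidia reads in total. Their read ratios, scaled to library size, were 825 (95% exact interval 228 to 6814), 895 (160 to 35366) and 640 (115 to 25317). The log2 fold change of CC1G_12454 was 9.56 with all libraries, 12.35 without oidia replicate 1 and 8.82 without oidia replicate 2, and that of CC1G_15645 was 9.09, 8.06 and 11.94. The values 14.95, 12.35 and 11.94 were fitted with no oidia read left, so they are not measured folds. With all libraries the 5 named genes of this direction had an adjusted p of at most 1.34e-164 (edgeR). In the other direction CC1G_04666 had 30308 ± 776 CPM in oidia against 1.53 ± 0.180 in hyphae (SD, n = 2 each), a log2 fold change of -14.27 with a standard error of 0.12. CC1G_03264, CC1G_14007, CC1G_04673 and CC1G_14884 followed with log2 fold changes of -10.67, -10.67, -10.20 and -9.90. That of CC1G_14007 was -11.405 without hyphae replicate 1.

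The oidia transcriptome was concentrated in few genes. The 10 most abundant genes took 39.1% ± 0.485 of gene reads in oidia and 12.2% ± 0.00910 in hyphae, and the 100 most abundant took 61.4% ± 0.340 and 31.6% ± 0.167 (SD, n = 2 each). Of the 13342 genes, 78.0% ± 0.551 had a read in oidia and 92.3% ± 3.39 in hyphae (SD, n = 2 each). The oidia libraries had more gene reads, but with so many in few genes their TMM-scaled sizes were smaller, 4426108 and 3552426 against 7852755 and 6038702. The floor that a count of 0 allows (3 reads over a stage) was 0.376 CPM in oidia and 0.216 CPM in hyphae. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Reads in hyphae and none in oidia were found for 2008 genes, of which 241 had enough reads to test. The opposite was found for 48 genes, of which 7 were tested. The gene filter used library sizes before TMM scaling, so a gene needed a higher scaled count in oidia to be tested. Repeats and centromeres with no oidia read held 0.604 and 0.272 reads per kb in hyphae replicates 1 and 2. A few hyphal reads in a gene therefore need not mean transcription. Log2 CPM correlated across genes, which are not independent replicates, at 0.991 within hyphae, 0.983 within oidia and 0.610 to 0.617 between stages.

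Most genes differed between the stages. Of 9866 genes tested, 8182 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, of which 4455 were higher in hyphae and 3727 lower. At least 4-fold changes were found for 3517 genes, 2069 higher in hyphae and 1448 higher in oidia. At least 64-fold changes were found for 431 genes, 319 higher in hyphae and 112 higher in oidia. Among all genes that passed, 241 had no oidia read and 7 had no hyphal read. Their fitted folds are not measured folds, and how many of them are among the 431 was not counted. The 64-fold counts and their lean towards hyphae therefore hold for fitted values only. The median absolute log2 fold change was 1.42. The split depended on the scaling of the libraries. TMM put 54.4% of the changed genes higher in hyphae, and scaling by total counts, added after the data were seen, put 82.7% there. The median log2 fold change of all tested genes was 0.25 with TMM, 0.17 with DESeq2 size factors, 0.51 with upper quartiles and 1.79 with total counts, so each direction is relative to that choice. The adjusted p in the authors' deposited table was under 0.05 for 7081 genes, 6991 of which also passed here in the same direction.

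Fold changes followed abundance. In the lowest-abundance decile of tested genes the median log2 fold change was 1.46, and in the highest it was -1.46. Abundance was averaged over the same 4 libraries, so the sign of this trend depends on which stage has the wider spread of abundance. Oidia reads were concentrated in few genes, so the trend is not independent of that result. With total-count scaling the medians of the same genes were 2.98 and 0.09, and those of deciles redrawn under that scaling 2.97 and 0.55.

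**Figure D1:**
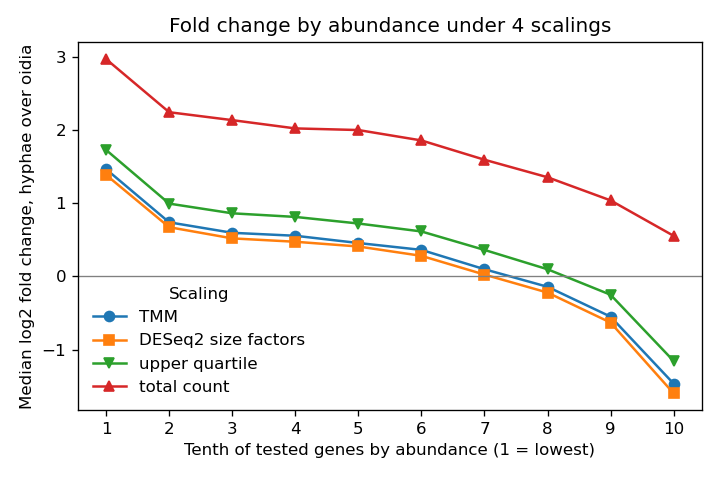
Median log2 fold change (hyphae over oidia, y axis) in each decile of tested genes by abundance (x axis, 1 is the lowest) under 4 scalings, 1 line each, with deciles redrawn under each scaling. Each line falls, from 1.46 to -1.46 with TMM and from 2.97 to 0.55 with total counts.

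Large changes were more common among paralogous and orphan regions than among orthologous ones. These class names are the table's own, and the classes were compared after the data were seen. At least 4-fold changes were found in 48.5% of 1792 tested paralogous regions, 42.0% of 2268 orphan regions and 29.0% of 5516 orthologous regions. The odds for orthologous against paralogous regions were 0.433 (95% interval 0.388 to 0.484, Fisher's exact test, two-sided, adjusted p = 1.45e-49 over 6 tests), and against orphan regions 0.564 (0.509 to 0.625, adjusted p = 1.41e-27). Log2 fold changes of next neighbours along the chromosomes were correlated (rank correlation 0.213), so the regions are not independent. Within deciles of abundance the common odds for paralogous over orthologous regions were 2.25 (2.00 to 2.54), and for orphan over orthologous regions 1.71 (1.54 to 1.90). With total-count scaling the odds were 1.91 and 1.32, against 2.31 and 1.77 with TMM. Paralogous regions that changed were higher in hyphae in 868 cases and lower in 606. These counts were 1459 and 292 with total-count scaling, and turned to 233 and 269 with a mean count of at least 100. With that filter orthologous regions were higher in hyphae in 1300 cases and lower in 1855. The lean was absent relative to orthologous regions with total-count scaling (odds ratio 0.977, 0.843 to 1.13, against 1.36, 1.20 to 1.53, with TMM). How reads that match several copies were counted is not given in the sources used here, so values of single paralogous regions are uncertain. Only 48.2% of paralogous regions had enough reads to test, against 94.6% of orthologous ones.

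**Figure D2:**
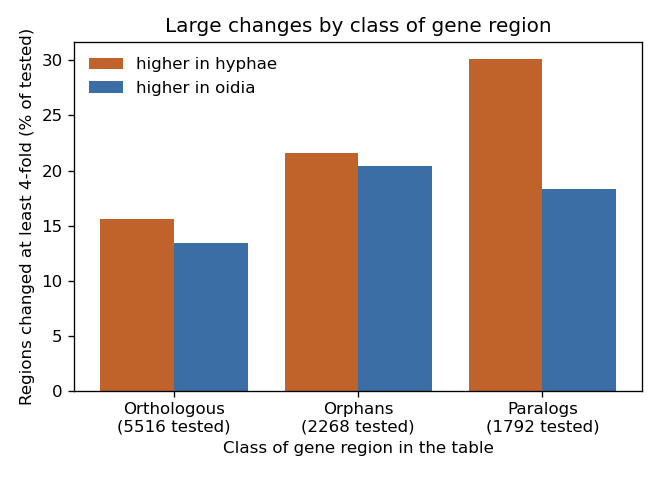
Share of tested regions (y axis, percent) that changed at least 4-fold with an adjusted p under 0.05, by class of gene region (x axis), with orange bars for regions higher in hyphae and blue bars for regions higher in oidia. Both directions together give 29.0% for orthologous, 42.0% for orphan and 48.5% for paralogous regions.

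Kyakuja and Dileera are families of DNA transposons, and the table lists separate rows for the transposase and for associated domains. Summed over a class, HMG rows of Kyakuja held 189 and 72 reads in the hyphae libraries and 2 and 1 in the oidia libraries, a log2 fold change of 5.54 ± 0.44 (SE, adjusted p = 1.96e-35, edgeR). Alpha-helix rows held 128 and 57 against 0 and 1. That single oidia read gives a scaled ratio of 106 with a 95% exact interval of 18.8 to 4219. Retroposon rows held 28 and 12 reads in hyphae against 0 and 1 in oidia, a scaled ratio of 23.0 (3.89 to 930). In hyphae replicates 1 and 2 they had 0.255 and 0.109 reads per kb. Repeats and centromeres with no oidia read had 0.604 and 0.272. The retroposon reads therefore cannot be told apart from background reads of the hyphae libraries. HMG rows were denser, at 2.16 and 0.824 reads per kb, as were alpha-helix rows, at 2.01 and 0.894. Their scaled ratios of hyphae replicate 1 to replicate 2 were 2.02 and 1.73, against 1.00 for orthologous regions. The repeats and centromeres with no oidia read also had this excess, so background may hold a part of these reads. The summed HMG, alpha-helix and retroposon rows stayed higher in hyphae under the 3 other scalings, with the replicate block and without each library. None of these alternatives removes background reads of the hyphae libraries. The HMG log2 fold change was 4.93 without hyphae replicate 1. The alpha-helix value was 5.46 without oidia replicate 1 and 9.34 without oidia replicate 2, and the retroposon value 3.26 and 7.14, against 6.48 and 4.28 with all libraries. The values 9.34 and 7.14 were fitted with no oidia read left, so they are not measured folds. The transposase and cys sums did not rise in hyphae with TMM. Kyakuja transposase rows had a log2 fold change of -0.47 ± 0.09 (SE, adjusted p = 1.0025e-06, edgeR), which turned to 1.08 with total-count scaling. Their oidia reads lay in 2 of the 55 intervals, and 51 had a read in hyphae. Dileera transposase rows had -1.26 ± 0.07 (SE, adjusted p = 6.25e-73, edgeR), which turned to 0.29. Of the 23 Dileera intervals, 20 had a read in hyphae and 7 in oidia. The Dileera sum rested on 5 tested rows. The 18 rows too sparse to test held 86 reads in hyphae and 7 in oidia. No stage difference is read from these 18, since they were set apart by their low counts. Cys rows of Kyakuja had 0.01 ± 0.24 (SE, adjusted p = 0.962, edgeR) and passed at 1.56 with total-count scaling. Of all 206 Kyakuja intervals, 179 had a read in hyphae and 13 in oidia, with some intervals listed in more than 1 class. The 6 intervals with enough reads to test held 98.8% of the oidia and 47.9% of the hyphal Kyakuja reads. In the other 200, hyphae replicate 1 had 598 reads and replicate 2 had 233, a ratio of 2.57 (95% exact interval 2.20 to 2.999) where gene reads had 1.29. The sum over all 206 Kyakuja intervals did not pass (log2 fold change 0.07 ± 0.09, SE, adjusted p = 0.548, edgeR). It was -0.24 without hyphae replicate 1, and passed at 0.33 without hyphae replicate 2 and at 0.33 with upper quartiles and 1.62 with total-count scaling.

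TET/JBP rows of Kyakuja behaved in more than 1 way. Of 46 members of the TET/JBP list 1 could be tested, a Kyakuja row on chromosome 11 from 1474589 to 1475961 (coordinates as in the table, whose genome build is not given in the sources used here). The chromosome 11 row had 2 and 2 reads in hyphae and 19 and 13 in oidia, a log2 fold change of -3.70 ± 0.63 (SE, adjusted p = 8.51e-09, edgeR). It passed also when adjusted over the list alone, but with 1 tested member that adjustment changes nothing. With a mean count of at least 100 it was not tested. Its log2 fold change was -2.20 with total-count scaling. A second row, on chromosome 6 from 36636 to 44358, had 28 and 11 reads in hyphae and 0 and 0 in oidia, at least 7.47-fold against a floor of 3 reads. The table lists this interval also as a Kyakuja transposase and as a Kyakuja alpha-helix row. The sums of these classes therefore share its reads. Too sparse to be tested with TMM and all libraries, the row passed as higher in hyphae with upper quartiles, total-count scaling, no low-count filter, and without hyphae replicate 2, oidia replicate 1 or oidia replicate 2. The chromosome 11 row held 97.0% of all oidia reads in the class. Of the 45 rows of the class, 40 had a read in hyphae and 2 in oidia. Summed over these rows the class was higher in hyphae (log2 fold change 1.34 ± 0.30, SE, adjusted p = 1.24e-05, edgeR). The rows had 1.42 and 0.731 reads per kb in hyphae replicates 1 and 2, where repeats and centromeres with no oidia read had 0.604 and 0.272. Background reads of the hyphae libraries may hold a part of this sum and of the chromosome 6 reads. No scaling or fit used here removes them. The sum was 2.88 with total-count scaling and 1.04 without hyphae replicate 1 (adjusted p = 0.0348, edgeR). CC1G_05589, the gene taken from the literature as a TET homologue, had 2 reads in hyphae replicate 1 and none in the other libraries, too few for a fold change.

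The transposon list fixed before the data were examined had 78 members, 7 of them tested and 5 past the threshold, 1 higher in hyphae and 4 lower. The direction of the split was not stable, with 5 higher and 2 lower under total-count scaling, 2 and 3 with upper quartiles, 9 and 4 with no low-count filter and 0 and 4 with a mean count of at least 100. Adjusted over the list alone the count was also 5. A Dileera transposase on chromosome 6 from 1074499 to 1078938 had a log2 fold change of -2.71 ± 0.10 (SE), and a Kyakuja transposase on chromosome 4 from 55380 to 60250 had -2.60 ± 0.15. Both stayed lower in hyphae with total-count scaling, at -1.16 and -1.06. A Dileera transposase on chromosome 1 from 3361521 to 3364531 had -1.48 ± 0.09 and turned to 0.07 with total-count scaling. The one on chromosome 9 from 1630277 to 1635250 had -0.36 ± 0.11 and turned to 1.19 with total-count scaling and to -0.09 (adjusted p = 0.419, edgeR) with upper quartiles. The 2 others did not pass, at -0.28 on chromosome 10 from 864716 to 869337 (Dileera) and -0.07 for a Kyakuja transposase on chromosome 11, but with total-count scaling both passed as higher in hyphae, at 1.26 (adjusted p = 2.39e-11, edgeR) and 1.48 (adjusted p = 1.28e-24, edgeR). The calls of the chromosome 9 and chromosome 10 rows also depended on which library was left out. The member that was higher in hyphae, a Dileera transposase on chromosome 3 from 3333207 to 3336353, had 2.22 ± 0.25. Against other rows the list as a whole did not pass (camera, adjusted p = 0.530 over 7 lists, and adjusted p = 0.648 with an estimated correlation). The 6 other lists were element classes used after the data were seen. With camera 0 of the 7 passed, and 0 had an unadjusted p under 0.05. Camera put the orphan and orthologous lists lower than other rows, although their medians were 0.04 and 0.08. By fry, which asks whether a list's rows move one way on balance without comparing them with other rows, 6 passed, the transposon list among them (adjusted p = 0.00160).

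**Figure D3:**
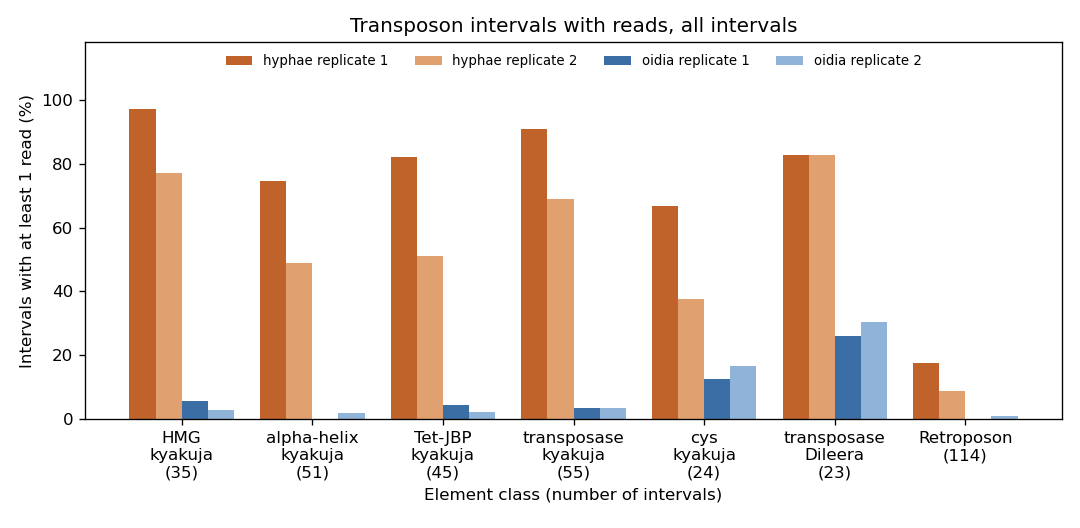
Share of all intervals with at least 1 read (y axis, percent) in each of the 4 libraries, one bar per library, by transposon class (x axis, with the number of intervals). Both hyphae libraries stand above both oidia libraries in each of the 7 classes drawn, from 97.1% and 77.1% against 5.71% and 2.86% of HMG intervals to 17.5% and 8.77% against 0% and 0.877% of retroposon intervals. The skew was not confined to the classes drawn. Of 900 rows classed as repeats, 363 and 267 had a read in hyphae replicates 1 and 2, against 88 and 90 in oidia. The bars count intervals, not reads, and summed reads of both transposase classes were lower in hyphae with TMM and higher with total-count scaling.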

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

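Total-count scaling, cyclic loess, fits of genes and elements together, and all alternatives for elements, class odds and medians were tests chosen after the data were seen. The count of changed genes stayed within 1.5 times of 8182 in 15 of 16 alternatives. It was 4603 (2386 higher, 2217 lower in hyphae) with a mean count of at least 100, where 5085 genes were tested, and 4581 for elements. For genes that filter also changed the TMM factors, which were computed on the kept genes. The 18 named genes moved by 0.163 to 0.4091 in log2, and 28 genes were opposite to the main fit. Total-count scaling gave 7407 genes higher and 1547 lower, with 1316 genes opposite to TMM. The replicate numbers did not pair the libraries (correlation of deviations -0.00844), and the replicate block gave 7928 genes. For 18 named genes, 233 of 234 alternatives kept direction and call; CC1G_10834 turned to 0.27 with cyclic loess. Values moved by over 1.5 times in 18 of the 18 with total-count scaling, 15 with cyclic loess (by up to 2.91 in log2), 3 without each oidia replicate, 1 without hyphae replicate 1 and 1 with the DESeq2 Wald test (CC1G_05776). Of the lists, 0 passed with camera and 6 with fry; Centromeres changed direction with fry (adjusted p = 0.008052). Directions of lists that did not pass also changed under the block for Centromeres, Orphans and Repetitive (adjusted p = 0.9456 each) and without hyphae replicate 1 (Centromeres, Orphans), hyphae replicate 2 (Orphans, Repetitive) and each oidia replicate (Repetitive). Over all 4 left-out libraries their adjusted p ran from 0.8646 to 0.948, 0.8646 to 0.9829 and 0.8257 to 0.9829. Total-count scaling turned the summed log2 fold changes of Centromeres to 0.13891, Orphans 0.26704, Paralogs 0.075715, Repetitive 1.5347, Dileera transposase 0.29415, Kyakuja transposase 1.0784 and all Dileera 0.29761. Repetitive turned to 0.2531 with upper quartiles. Signs of sums that did not pass changed with DESeq2 size factors for Dirs1 (-0.046393), cys (-0.066426) and all Kyakuja (-0.014431), and with the block for cys (-0.01948). Without single libraries the ranges were -0.27988 to 0.26142 for Repetitive (which passed higher without hyphae replicate 1, adjusted p = 0.002126, and lower without hyphae replicate 2, adjusted p = 0.001148), -0.13074 to 0.26181 for Dirs1, -0.52746 to 0.37 for cys and -0.23752 to 0.32742 for all Kyakuja. Total-count scaling also turned the Dileera transposases on chromosome 10 (1.2648), chromosome 1 (0.065471) and chromosome 9 (1.1896), the Kyakuja transposase on chromosome 11 (1.4781, and 0.19639 with upper quartiles), the median of the highest decile of abundance (0.55442, or 0.087031 with its genes held fixed) and the odds of paralogous regions being higher (0.9767). The TMM factors, which differ between the stages, are left out of total-count scaling, and this moved fitted values towards hyphae. With TMM the sums had been -1.4106 for Centromeres, -1.2824 for Orphans, -1.4741 for Paralogs and -0.013739 for Repetitive. The 18 named genes moved by 0.768 to 1.5507 in log2 with total-count scaling. The smallest move was that of CC1G_05776, which had no oidia read. The cause of the changes under the other alternatives was not tested. GC correction, pseudocounts for normalized values and list membership from a second source were not run.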

Other observations

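The tests on the Kyakuja elements, on the trend with abundance, on next neighbours at least 1 kb apart and of 4-fold changes near chromosome ends were chosen after the results they follow up were seen. For the replicate ratio by decile and the neighbours at least 1 kb apart, predictions were written before those values were computed. Replicate ratios of whole classes had been seen by then.

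Of 206 Kyakuja intervals, 179 had a read in hyphae and 13 in oidia, and thinning hyphae reads to the scaled depth of oidia leaves an expected 160.268 (SD 3.64), so sequencing depth is not the cause of that spread. Depth was not excluded for the reads: their ratio was 1.85 (95% exact interval 1.70 to 2.01) over all intervals, where scaled sizes had 1.74, and the 83.1 over untested intervals decides nothing, since testing removed 98.8% of oidia reads from them. Background reads over untranscribed sequence of the hyphae libraries may account for a part. Repeats and centromeres with no oidia read had a ratio of hyphae replicate 1 to replicate 2 of 2.2162 (1.76 to 2.80), near the 2.57 of untested Kyakuja intervals and above the 1.29 of genes, but only 39.4% and 45.6% of their read density. How background varies between kinds of sequence was not measured, so background, transcription in hyphae and the library kits cannot be told apart.

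The trend of fold change with abundance had a rank correlation of -0.331 across 9576 regions, which are not independent replicates. It was -0.3194 with region length held constant, so length is not the whole cause. Subtracting 1 density of silent sequence from every region left -0.3222, which assumes even background and decides nothing, but the hyphae replicates had a read ratio of only 1.33 in the lowest decile (genes 1.29), and removing the largest background share this allows left a gap between the outer deciles of 2.5382 (from 2.79), so background with the replicate ratio of silent sequence is not the whole cause. The gap over genes, with deciles held fixed, was at least 2.8923 under 4 scalings, but 1 factor per library can hardly change that gap, so this test decides nothing. Abundance was averaged over the same libraries, so the trend is not independent of the concentration of oidia reads. Stage and library kit cannot be told apart.

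Next neighbours changed together, with a rank correlation of log2 fold changes of 0.213 over 7872 pairs against 0.0227 as the upper limit of the central 95% of 1000 permuted orders (permutation p = 0.001 one-sided, the smallest they can give). For the third neighbour it was 0.0414, and 0.042 with class medians removed, above that limit of their own permuted orders, while the fifth (0.0104) and the tenth neighbour (0.00083) lay below it. Reads counted in an adjacent region and clustering by class are therefore not the whole cause, since 0 of 13223 adjacent pairs overlapped and pairs at least 1 kb apart still had 0.1786. Tandem copies that share reads, and biological explanations, were not tested.

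Regions within 100 kb of the outermost listed region of a chromosome did not lean towards hyphae, with an odds ratio of higher against lower calls of 0.8871 (Fisher's exact test, two-sided p = 0.277). At least 4-fold changes were found in 49.3% of tested regions there and 35.1% elsewhere (odds ratio 1.80, Fisher's exact test, two-sided p = 8.39e-09, with neighbours not independent). Of 917 regions near the ends, 203 changed at least 4-fold, 209 were tested without such a change and the rest were not tested. Class and abundance were not held constant, so an effect of position is not shown.

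The longest run of adjacent regions each at least 4-fold higher in hyphae held 7 regions, on chromosome 7 from 571595 to 585936. The longest run higher in oidia held 6 regions, on chromosome 2 from 2711683 to 2722291. For each, 5 of 200 permuted orders had a run as long.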
